A study of Mus musculus with 6 samples.

How the data were processed

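Total RNA of 6 samples of mouse embryonic stem cells, 3 WT and 3 Mutant, was extracted with Trizol-LS and made into libraries with a stranded total RNA kit (TruSeq), per the labels' protocols. The deposited table holds raw counts per gene symbol for 24061 symbols, not normalised. Per the submitters' processing notes the tools were HISAT2 2.0.4 and HTSeq, and the genome build was mm10. The version of HTSeq, its strand setting, the gene annotation, the read length and any filter are not given in the sources used here. A stranded kit marks the strand of each read, but without the counting setting the reads of overlapping genes on opposite strands cannot be assigned with certainty, so some overlaps are stated beside the genes. In addition, exons of Cdkn1a, Ctsl, Cubn, Dnmt3a, Eif2ak2, Gata6, Krt8, Me1, Nnat, Pdgfra and Sox21 overlap an annotated gene on the opposite strand, and those of Ctsl, Fdps, Pdgfra and Sox1 overlap a predicted or microRNA gene on the same strand, so their values carry the same limit. A total RNA kit also keeps unspliced and non-polyadenylated RNA, so that counts of introns near exons and of histone genes depend on the counting rules.

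Genotype and replicate number were taken from the sample titles. Of the symbols, 22710 (94.4%) matched exactly 1 gene of GENCODE M21 (GRCm38, the build also called mm10), which gave positions, strand, overlapping exons, transcript length and GC content. Symbols without such a match, Ddit3 among the named genes, have no position here. All rows of the table named a gene. Totals per library ran from 16075985 to 59431913 counts, and the 10 most abundant genes took between 6.31% and 6.75% of them. A chi-square test per pair of libraries of one genotype, over genes with more than 20 counts in sum, gave 1.27 (WT 1 and 2) or more per degree of freedom. Every pair thus differed by more than sampling noise, and all 6 libraries were counted as separate samples. Such a test cannot tell technical from biological replicates.

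Counts were tested in R 4.3.3 with edgeR 4.0.16, by a quasi-likelihood F-test (robust, genotype as the only term) after TMM scaling and the filterByExpr filter, which left 13515 genes with at least 99.94% of the counts. TMM factors lay between 0.983 and 1.013, and the biological coefficient of variation was 0.045. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are Mutant minus WT, with a prior count of 0.125, and each SE was taken from the fold change and its F statistic. CPM values are TMM-scaled, and their errors are SDs over 3 libraries. Normalisation, the test, the filter, the alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. The rule names the eIF2B subunits and the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, leaving out predicted genes and pseudogenes. It also names up to 3 members with the smallest adjusted p of each of the first 7 lists and up to 2 of each other list, up to 1 called member that goes the other way, and Atf4, Ddit3, Trib3, Asns, Chac1 and Atf3 whatever their values.

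The lists cover regulators of the integrated stress response, serine and one-carbon metabolism, amino acid synthesis, amino acid transporters, cytosolic and mitochondrial tRNA synthetases, chaperones of the endoplasmic reticulum, eIF2 and eIF2B with the eIF2 kinases, other initiation and elongation factors, and cytosolic ribosomal proteins. They also cover nuclear and mitochondrial respiratory chain genes, mitochondrial chaperones, glycolysis, cholesterol synthesis, NRF2, heat shock and p53 targets, autophagy, naive, formative and 2-cell-like states, and neuroectoderm, mesoderm, endoderm, trophectoderm, fibroblast and glial markers. The rest are germline, imprinted, cell cycle, histone, immediate early and Y-linked genes. Of these, 32 lists had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over those lists. Camera called 7 lists higher and 11 lower. With a correlation estimated per list it called 0 (10 at an unadjusted p under 0.05, smallest adjusted p = 0.0636), and fry, which tests whether a list moves on balance one way without comparing it with other genes, called 10 higher and 8 lower. For cholesterol synthesis, fibroblast, p53 and mesoderm genes the estimated correlation was -0.003, -0.004, -0.032 and -0.06, below the preset value. It was also below that value for immediate early genes (0.007), mitochondrial chaperones (0.004) and mitochondrial tRNA synthetases (0). The lost calls of all these lists therefore do not show that correlation among the members accounts for the shift.

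The pipeline was tested on simulated data for this comparison, with 200 of 13515 genes changed and a short further list of genes shifted. EdgeR recovered 52% of genes changed 1.2-fold, 86% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 9 false calls, so changes near 1.2-fold were often missed in that simulation. The data hold 2557 called genes, which makes the adjusted threshold looser there, so these shares need not carry over. The alternatives were DESeq2 size factors, scaling by library size only, no filter, a CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0 and limma-voom as tests, the replicate number as a block, leaving out each library in turn, a fold threshold, other prior counts, and estimated correlation or fry for lists. Thinning every library at random to the smallest total was added after seeing that the Mutant libraries were deeper. Chromosome medians were set against 10000 random gene sets of the same size matched on mean expression.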

Results

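RNA sequencing of total RNA was used to compare mouse embryonic stem cells that are homozygous for an edited Eif2b5 gene (Mutant) with unedited cells (WT). Eif2b5 encodes the epsilon subunit of eIF2B, the guanine nucleotide exchange factor that reloads eIF2 with GTP so that translation can start. Phosphorylated eIF2 inhibits eIF2B, and this block starts the integrated stress response, in which general translation falls while the transcription factor ATF4 is made in larger amounts. The change R191H was made with CRISPR/Cas9, a nuclease directed by a guide RNA. In the GRCm38 annotation, residue 191 is encoded on chromosome 16 at 20501706 to 20501708, in exon 4 of the 16 coding exons of the full-length Eif2b5 transcript, where the reference codon CGC encodes arginine. The comparison asks which transcripts differ between cells with this change and WT cells. There were 3 libraries per genotype. The table gave 16075985, 18927326 and 16462931 counts for WT 1, 2 and 3, and 20688232, 59431913 and 29220646 for Mutant 1, 2 and 3, so the Mutant libraries were the deeper ones. At these depths 3 counts correspond to between 0.0505 CPM (counts scaled to library size) in Mutant 2 and 0.187 CPM in WT 1. Nothing in the labels says that the libraries came from separate cultures or clones. The p-values therefore measure only the spread between these libraries, which may be technical, and genotype cannot be told apart from clone.

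The first principal component held 55.5% of the variance and separated the genotypes, and the second held 16.5%. Correlations of log2 CPM were at least 0.9943 between libraries of one genotype and at most 0.9918 between genotypes. Of 13515 genes tested, 1519 were higher and 1038 were lower in Mutant cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Higher genes made up 59.4% of the calls, and 47.1% with the replicate number as a block. With scaling by library size only, 1869 genes were higher and 704 lower, which put 72.6% of the calls on the higher side. Most changes were small. The median fold was 1.3 among the higher and 0.85 among the lower genes, and 197 higher and 19 lower genes changed by at least 1 on the log2 scale. The count of lower genes was 580 without WT 1, 528 without WT 2, 623 without Mutant 1 and 539 without Mutant 2. In 36.3% of the tested genes, 4905 in number, the WT and Mutant values did not overlap, where chance gives 10% for 3 against 3.

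Eif2b5 itself was among the genes that fell furthest. Its level was 198.7 ± 6.62 CPM in WT and 100.6 ± 0.847 CPM in Mutant cells (SD, n = 3), a log2 fold change of -0.98 ± 0.0417 (SE, edgeR adjusted p = 1.08e-08). The gene lies on chromosome 16 at 20498817 to 20509323 on the plus strand, and no annotated exon of another gene overlaps its exons. A point change need not alter transcript level, so this value does not check the labels. The 4 other eIF2B subunits were not called. Their log2 fold changes were -0.06 for Eif2b1, -0.05 for Eif2b2, -0.04 for Eif2b3 and -0.08 for Eif2b4, with edgeR adjusted p = 0.373, 0.497, 0.664 and 0.287. Exons of Eif2b4 overlap those of Snx17 on the opposite strand. Of the 12 eIF2 and eIF2B subunits and eIF2 kinases, Eif2b5 fell and Eif2ak2, the kinase PKR that is activated by double-stranded RNA, rose from 21.3 ± 1.34 to 27.1 ± 0.404 CPM (log2 fold change 0.35 ± 0.0591, edgeR adjusted p = 0.00118). Without WT 3, 2 members of this list were lower. The list as a whole did not pass the camera gene set test (adjusted p = 0.142), though fry called it (0.0075). The nearest tested genes were Abcc5, 72.4 kb away towards lower coordinates, at 0.03 ± 0.0477, and Dvl3, 7.66 kb away on the other side, at 0.10 ± 0.0501, and neither was called (edgeR adjusted p = 0.743 and 0.17).

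**Figure D1:**
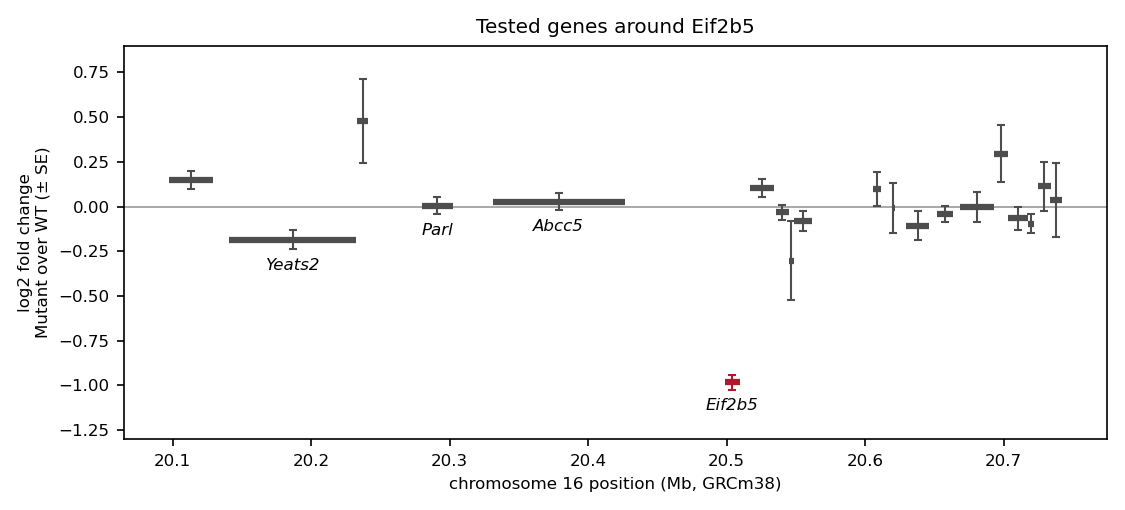
Log2 fold change (Mutant over WT, edgeR) of the tested genes within 500 kb of Eif2b5, plotted against position on chromosome 16 in Mb (GRCm38); each thick bar spans a gene and thin bars are ± 1 SE of a fit to 3 libraries per genotype. Eif2b5 (red) stands at -0.98, while Abcc5, Parl and Yeats2 stand at 0.03, 0.01 and -0.19. Of these neighbours, Yeats2 was also called lower (edgeR adjusted p = 0.0269).

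Genes of the integrated stress response changed unevenly. Transcripts of Atf4, its main transcription factor, rose from 41.3 ± 0.209 to 56.3 ± 2.47 CPM (log2 fold change 0.45 ± 0.0485, edgeR adjusted p = 4.33e-05). Those of Atf3, a stress-induced factor downstream of it, rose from 3.97 ± 0.358 to 6.98 ± 0.498 CPM (0.81 ± 0.112 on the log2 scale, edgeR adjusted p = 0.000287). Ddit3, which encodes CHOP, stood at 3.75 ± 0.678 CPM in WT and 4.17 ± 0.119 CPM in Mutant cells (adjusted p = 0.508). Trib3, a feedback inhibitor of ATF4, stood at 8.03 ± 1.17 and 7.99 ± 0.65 CPM (adjusted p = 0.845), and the sign of its log2 fold change of -0.04 turned to 0.04 without WT 2 and 0.03 without Mutant 2. Chac1, a glutathione-degrading enzyme, had a log2 fold change of 0.56 ± 0.184 (edgeR adjusted p = 0.0489), and this call was lost in each of the 6 fits that left out 1 library, where the adjusted p lay between 0.0812 and 0.155, with no filter on low counts (0.0571), and with DESeq2 (0.165) and limma-voom (0.0574). Sesn2, which restrains mTORC1, fell by 0.19 ± 0.0413 on the log2 scale (edgeR adjusted p = 0.00569). In all, 3 of 18 tested regulators and reporters of the response were higher and 2 lower, and 4 and 2 adjusted over the list alone. Only 1 was lower without WT 2, WT 3, Mutant 1 or Mutant 2, and 2 were higher without any 1 library other than WT 3. Camera called this list higher (adjusted p = 0.0479; adjusted p = 0.351 with an estimated correlation). That call was lost without WT 1, WT 3 or Mutant 3 (adjusted p = 0.136, 0.0507 and 0.146), and with scaling by library size only (adjusted p = 0.0648). It was also lost with no filter on low counts (0.0552), with the stricter filter on CPM (0.0608) and after thinning to the smallest library (0.0963). Across the alternatives that kept the preset correlation its largest adjusted p was 0.146.

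Amino acid genes, many of which ATF4 is known to control, showed a few called members per list. Asns, asparagine synthetase, rose from 197.1 ± 8.31 to 253.4 ± 10.1 CPM (log2 fold change 0.36 ± 0.0477, edgeR adjusted p = 0.000193). Of 14 genes for synthesis and interconversion of amino acids, Asns included, 4 were higher and 1 lower over all genes tested and adjusted over the list alone. They included Cth, which makes cysteine, at 0.37 ± 0.0586, and Oat, ornithine aminotransferase, at 0.56 ± 0.0623 on the log2 scale. The lower member was Got1, an aspartate aminotransferase, at -0.15 ± 0.0418 (edgeR adjusted p = 0.0279), which was not called without WT 1, WT 2, Mutant 1, Mutant 2 or Mutant 3 (adjusted p between 0.0625 and 0.131) or with library size only (0.0638) or thinning (0.0652). Of 12 tested plasma membrane amino acid transporters 4 were higher and none lower, with the same 4 and 0 adjusted over the list alone. Slc7a11 and Slc6a9, also in that list, fell below the count filter and were not tested. They had 1 and 13 counts in all WT and 3 and 46 in all Mutant libraries. Slc7a1, which carries cationic amino acids, had a log2 fold change of 0.50 ± 0.0678, and Slc1a4, which carries neutral ones, 0.49 ± 0.112 (edgeR adjusted p = 0.000257 and 0.00849). Without WT 2, 2 transporters were called higher, without WT 1, Mutant 1 or Mutant 2, 3, and without WT 3, 5 higher and 1 lower. Aldh1l2 of the serine and one-carbon list was likewise not tested, with 16 counts in all WT and 40 in all Mutant libraries. Of the 13 tested genes of that list 2 were higher over all genes and over the list alone. Of these, Phgdh, the first enzyme of serine synthesis, stood at 0.20 ± 0.041 with the smaller adjusted p (edgeR adjusted p = 0.00509). Without WT 1 or Mutant 2 the count was 1, and without WT 3 it was 1 higher and 2 lower. Camera called none of these 3 lists, with adjusted p = 0.218 for amino acid synthesis, 0.143 for transporters and 0.519 for serine and one-carbon genes. Before adjustment, their camera p-values were 0.177, 0.112 and 0.486. Fry called the transporters (adjusted p = 0.00427).

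Cytosolic aminoacyl-tRNA synthetases, also known ATF4 targets, showed no called member among 22 with edgeR, DESeq2 or limma-voom. At an unadjusted edgeR p under 0.05, 0 were higher and 1 lower, and 1 was called lower by edgeR without WT 3. Their median log2 fold change was -0.02, which turned to 0.02 with scaling by library size only, and camera gave an adjusted p of 0.348. Of the 19 chaperones and degradation genes of the endoplasmic reticulum, edgeR called 0 higher and 2 lower, and 0 and 0 adjusted over the list alone. DESeq2 called 0 of them, and at an unadjusted edgeR p under 0.05 the counts were 0 higher and 4 lower. The called pair were Hyou1, a chaperone, and Xbp1, a transcription factor of the unfolded protein response, with log2 fold changes of -0.15 and -0.13. Each of these calls was lost in 5 of the 6 fits that left out 1 library, with adjusted p up to 0.131 and 0.132. The median of this list was -0.01, which turned to 0.02 with library size only, and camera gave an adjusted p of 0.299.

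**Figure D2:**
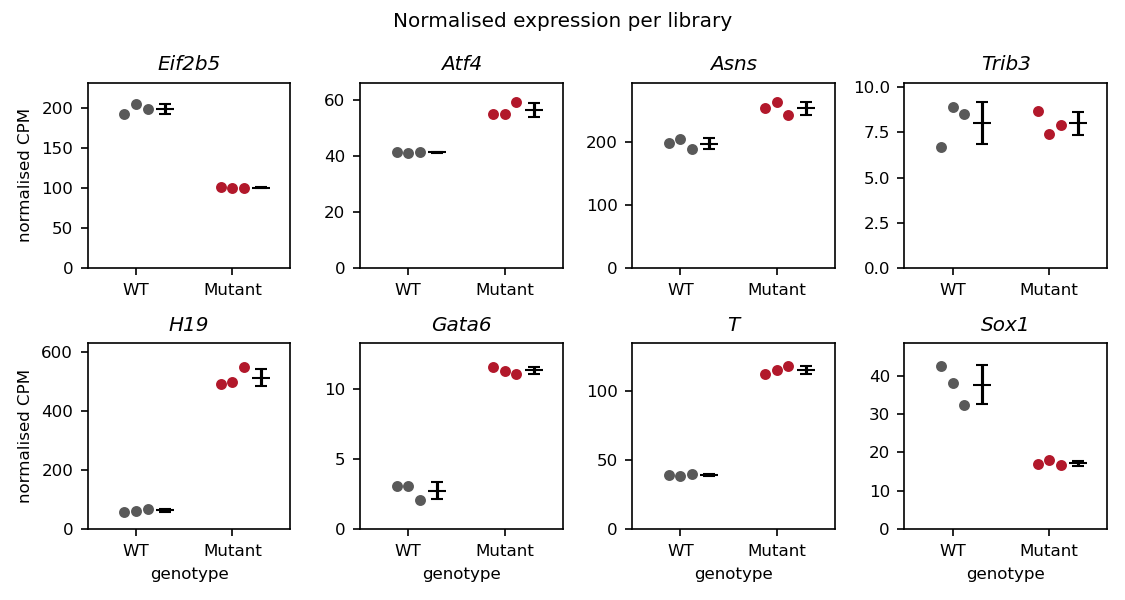
Normalised expression in CPM (y axis, from 0) in each library of 8 genes, by genotype (x axis); points are the 3 WT (grey) and 3 Mutant (red) libraries, and the bar beside them is the mean ± SD. All 3 Mutant libraries lie below all 3 WT libraries for Eif2b5 and Sox1 and above them for Atf4, Asns, H19, Gata6 and T, while those of Trib3 overlap.

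The endoderm list had the largest median change of the lists tested by camera. Among its 16 tested markers, of primitive and definitive endoderm, 13 were higher in Mutant cells and 0 lower, with the same counts adjusted over the list alone and a median log2 fold change of 1.88. Col4a1, a basement membrane collagen chain, rose from 20.03 ± 2.55 to 83.4 ± 4.35 CPM (log2 fold change 2.06 ± 0.0739, edgeR adjusted p = 2.26e-09), and Lama1, a laminin chain, from 19.07 ± 0.256 to 62.4 ± 1.45 CPM. Gata6, a transcription factor that specifies primitive endoderm, rose from 2.74 ± 0.585 to 11.3 ± 0.242 CPM (2.03 ± 0.119, edgeR adjusted p = 2.16e-07). Cubn, an endocytic receptor of visceral endoderm, Sox7, another endodermal transcription factor, and Col4a2 also stood among the 6 largest rises, at 2.12 ± 0.116, 1.83 ± 0.116 and 1.94 ± 0.0865. Col4a1 and Col4a2 overlap at their first exons on opposite strands, and the strand setting of the counting is not given in the sources used here. Camera called the endoderm list higher (adjusted p = 1.93e-17; adjusted p = 0.0636 with an estimated correlation).

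Markers of other lineages moved both ways. Of 13 primitive streak and mesoderm markers 6 were higher and 0 lower, and 7 and 0 adjusted over the list alone. T (Brachyury), the T-box factor of the primitive streak, rose from 39.3 ± 0.456 to 115.4 ± 3.1 CPM (log2 fold change 1.55 ± 0.0442, edgeR adjusted p = 2.34e-10), and Tbx20 rose by 1.53 ± 0.105. Of 9 trophectoderm markers 5 were higher and 1 lower in both counts, and Hand1 is in both this list and the mesoderm list. The keratins Krt18 and Krt8 rose by 1.05 ± 0.0399 and 0.92 ± 0.0516, and Tfap2c, a trophoblast factor also made in stem cells, fell by 0.38 ± 0.0429. Of 15 embryonic fibroblast markers 8 were higher (9 adjusted over the list alone) and 0 lower, among them Sparc at 0.88 ± 0.0453 and Acta2 at 0.61 ± 0.0448, and 7 were higher without any 1 WT library and 5 without Mutant 2. In contrast, 4 of 8 neuroectoderm markers were lower and 0 higher in both counts. Sox1, a factor of early neural cells, fell from 37.7 ± 5.07 to 17.1 ± 0.737 CPM (-1.13 ± 0.0837, edgeR adjusted p = 1.51e-06), and Pax6 from 46.3 ± 1.76 to 25.6 ± 1.37 CPM (-0.85 ± 0.0561, edgeR adjusted p = 5.28e-07). The neural factors Sox21 and Olig3, which were in no list, were also among the 6 largest falls, at -1.03 ± 0.0942 and -0.82 ± 0.0778, as was Myo1f, an unconventional myosin, at -0.76 ± 0.119. Camera called mesoderm (adjusted p = 0.000257), trophectoderm (0.00303) and fibroblast markers (3.32e-05) higher and neuroectoderm (0.00906) lower. With an estimated correlation the adjusted p was 0.078, 0.15, 0.0636 and 0.15. Of 6 glial markers 2 were higher, Mbp at 0.40 and Pdgfra at 2.55 on the log2 scale, and Pdgfra was also in the endoderm list. The glial list did not pass camera (adjusted p = 0.0994), but it did with the stricter filter on CPM (0.0283). Fry, which does not compare a list with other genes, also called it (adjusted p = 4.51e-05).

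**Figure D3:**
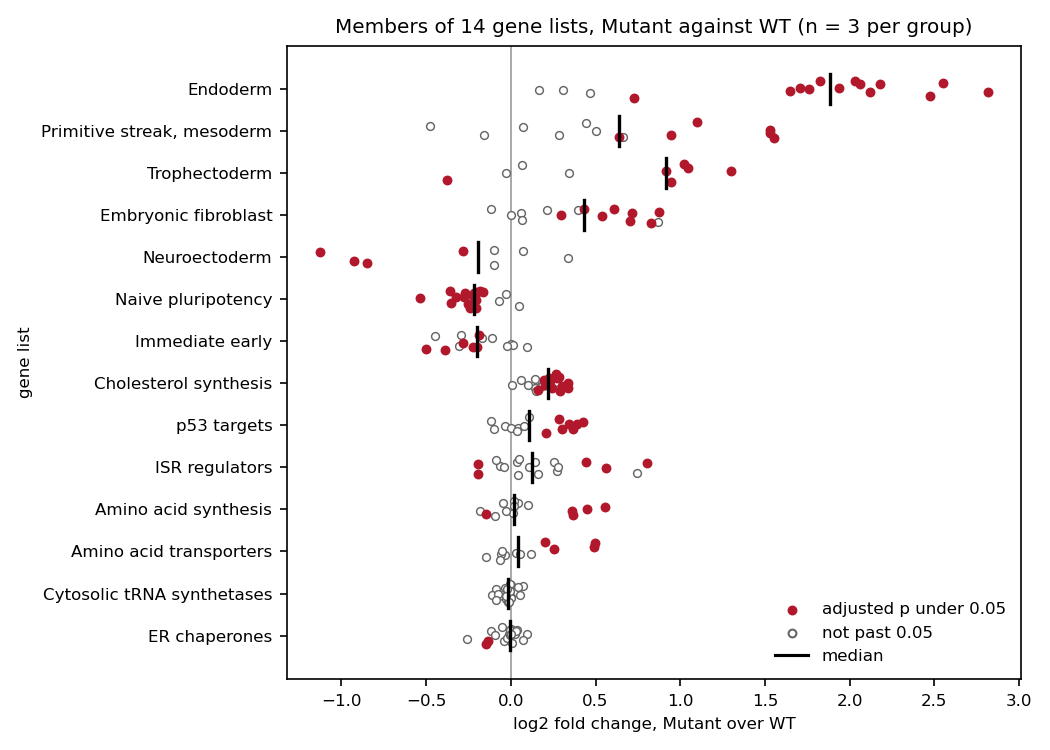
Log2 fold change (x axis, Mutant over WT, edgeR, 3 libraries per genotype) of each tested member of 14 gene lists (rows). Filled red points have an adjusted p under 0.05, open points do not, and black bars are list medians, which stand at 1.88 for endoderm, -0.22 for naive pluripotency and -0.02 for cytosolic tRNA synthetases; the last turns to 0.02 with scaling by library size only, and the median of the endoplasmic reticulum list turns from -0.01 to 0.02.

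Of 19 naive pluripotency genes 16 were lower and 0 higher, over all genes and adjusted over the list alone, with a median log2 fold change of -0.22 in the same libraries in which the endoderm median stood at 1.88. Nr0b1, a nuclear receptor of naive cells, fell from 104.3 ± 3.2 to 71.7 ± 1.39 CPM (-0.54 ± 0.0422, edgeR adjusted p = 2.54e-06). Zfp42, which encodes REX1, fell from 422.5 ± 4.33 to 329.5 ± 2.24 CPM (-0.36 ± 0.0413, edgeR adjusted p = 6.52e-05). With 1 library left out the count of lower members ran from 10 (without WT 2) to 16 (without Mutant 3). Camera called the list lower (adjusted p = 3.45e-08; adjusted p = 0.0636 with an estimated correlation). Of 12 formative and primed markers 3 were higher and 4 lower, and 3 and 6 adjusted over the list alone. Fgf5, a growth factor of the formative state, rose from 22.7 ± 1.91 to 44.98 ± 2.01 CPM (0.98 ± 0.0639, edgeR adjusted p = 4.8e-07), and Dnmt3a, a DNA methyltransferase, fell by 0.41 ± 0.0448. The counts were 1 higher and 3 lower without WT 1, WT 2 or Mutant 2, 2 and 4 without Mutant 1, and 3 and 5 without WT 3 or Mutant 3, and camera gave an adjusted p of 0.328. Of 10 markers of the 2-cell-like state 0 were higher and 1 lower in both counts. This was Zscan4a at -0.56 ± 0.115 (edgeR adjusted p = 0.00432), annotated as an unprocessed pseudogene, whose reads can be shared with near-identical family members. That list had a camera adjusted p of 0.0994, which was 0.0328 without WT 2 and 0.0325 with no filter on low counts.

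H19, an imprinted long noncoding RNA on chromosome 7 at 142575529 to 142578143, had the largest rise among named genes with a mean of at least 5 CPM. It went from 63.1 ± 5.62 CPM in WT to 513.3 ± 29.8 CPM in Mutant cells, 8.14-fold higher (edgeR adjusted p = 1.84e-11). Its exons overlap the microRNA gene Mir675 and a pair of predicted genes on the opposite strand. Of 27 imprinted genes 8 were higher and 4 lower, and 10 and 5 adjusted over the list alone, and 2 were lower without WT 1, 3 without Mutant 1, and 6 were higher and 3 lower without Mutant 2. They included Nnat, a membrane protein gene, at 0.74 ± 0.064 and Phlda2, a regulator of placental growth, at -0.44 ± 0.061. This list did not pass camera (adjusted p = 0.142), though fry called it (adjusted p = 0.000964). Of 12 germline genes normally silenced by promoter methylation 0 were higher and 3 lower, 4 adjusted over the list alone, among them Tex19.1 at -0.27 ± 0.0587 and Sycp3 at -0.28 ± 0.0605, whose exons overlap Chpt1 on the opposite strand. With 1 library left out, 2 to 4 germline genes were lower. Camera called the germline list lower (adjusted p = 0.0114; adjusted p = 0.432 with an estimated correlation), and the call was lost with no filter on low counts (0.0504). It was also lost after thinning to the smallest library (0.0567), which took the adjusted p of Tex19.1 to 0.107, and fry did not call the list (0.112).

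Of 23 tested cholesterol synthesis genes, 14 were higher and 0 lower, 17 and 0 adjusted over the list alone, with a median log2 fold change of 0.22. Cyp51, which demethylates lanosterol, rose from 40.7 ± 1.55 to 51.4 ± 0.921 CPM (0.34 ± 0.0477, edgeR adjusted p = 0.000331). Fdps, farnesyl diphosphate synthase, rose from 115.2 ± 1.66 to 140.1 ± 1.04 CPM (0.28 ± 0.0389, edgeR adjusted p = 0.000279). Exons of Cyp51 overlap those of Akap9 on the opposite strand. Camera called the list higher (adjusted p = 1.01e-07; adjusted p = 0.0636 with an estimated correlation). Of 15 p53 targets 7 were higher and 0 lower, 8 and 0 adjusted over the list alone. They included Cdkn1a, the cell cycle inhibitor p21, at 0.43 ± 0.0471 and Ccng1, cyclin G1, at 0.39 ± 0.0434 (edgeR adjusted p = 4.57e-05 and 5.3e-05). Without Mutant 3, 7 were higher and 1 lower. The p53 list passed camera (adjusted p = 0.00569; adjusted p = 0.124 with an estimated correlation). Of 15 immediate early genes 6 were lower and 0 higher, 7 and 0 adjusted over the list alone. Among these, Egr1, a growth factor-induced transcription factor, fell by 0.50 ± 0.0519 and Spry4, a feedback inhibitor of that signalling, fell by 0.39 ± 0.0428 (camera adjusted p = 0.000434; adjusted p = 0.0847 with an estimated correlation).

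Of 13 NRF2 targets 2 were higher and 5 lower, 2 and 6 adjusted over the list alone, with Hmox1, heme oxygenase, at -0.31 ± 0.0385 and Me1, malic enzyme, at 0.37 ± 0.0495. The lower count was 3 without WT 1, WT 2 or Mutant 2, 4 without Mutant 1 and 6 without WT 3, and camera gave an adjusted p of 0.142. Of 12 heat shock genes 1 was higher and 2 lower in both counts, with the co-chaperone Bag3 at 0.26 ± 0.0562 and the chaperone Hsph1 at -0.26 ± 0.0613. Hsph1 was not called without WT 1 or WT 2 (adjusted p = 0.0546 and 0.0746), and 0 members were lower in either fit. There were 4 lower without WT 3 and 1 without Mutant 1 or Mutant 3. Camera called this list lower (adjusted p = 0.0247; adjusted p = 0.351 with an estimated correlation), but not without WT 1 (0.0572). Of 13 mitochondrial chaperones and proteases 3 were lower and 0 higher, 4 and 0 adjusted over the list alone. They included the protease Lonp1 at -0.18 ± 0.0384, and 1 was lower without WT 1, WT 2 or any Mutant library and 6 without WT 3 (camera adjusted p = 0.0114; adjusted p = 0.15 with an estimated correlation). Of 19 autophagy and lysosome genes 5 were higher and 4 lower in both counts, with the protease Ctsl at 0.40 ± 0.048 and the kinase Ulk1 at -0.27 ± 0.0469. Between 2 and 3 were higher, and between 2 and 3 lower, without WT 1, WT 2 or any 1 Mutant library, and camera gave an adjusted p of 0.764. Of 19 glycolytic genes 2 were higher and 0 lower in both counts. These were Eno3 and Aldoc, at 0.33 and 0.23, both lost without WT 2 (adjusted p = 0.0579 and 0.127), and Aldoc also without Mutant 1 (0.0764) or Mutant 2 (0.0891) and with DESeq2 (0.0547), and Eno3 after thinning (0.0588). Without WT 3, 1 glycolytic gene was lower, and without Mutant 3, 3 were higher. Camera gave this list an adjusted p of 0.846.

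Large lists of translation, respiration and cell cycle genes were called lower by camera on small shifts. The median log2 fold change was -0.05 for 78 cytosolic ribosomal protein genes, -0.06 for 74 nuclear-encoded respiratory chain genes, -0.06 for 24 cell cycle genes and -0.08 for 20 replication-dependent histone genes. With 1 library left out, the medians of these 4 lists ran from -0.101 to -0.006, -0.085 to -0.016, -0.098 to -0.018 and -0.149 to -0.042. Their camera adjusted p was 0.0479, 0.00632, 0.0414 and 0.0479, and 0.782, 0.65, 0.65 and 0.665 with an estimated correlation. Few members were called without the replicate number as a block, and more with it, as given further below. The counts higher and lower were 1 and 0 for ribosomal proteins, 0 and 1 for the respiratory chain, 0 and 2 for the cell cycle and 0 and 1 for histones. Adjusted over the list alone they were 0 and 0, 0 and 0, 0 and 1, and 0 and 1. The called members included Ccne1, cyclin E1, at -0.23 ± 0.0395 and Hist1h4h at -0.42 ± 0.0737. Without WT 3, the camera adjusted p was 0.884 for ribosomal proteins, 0.152 for the respiratory chain and 0.152 for histones, and without Mutant 1 it was 0.676, 0.145 and 0.299. Ribosomal proteins also lost the call without Mutant 2 (0.268), histones without WT 2 (0.0586) or Mutant 2 (0.14), and the cell cycle list without WT 1 (0.152), WT 2 (0.122) or Mutant 3 (0.246). Without Mutant 3, 4 ribosomal protein, 11 respiratory chain and 9 histone genes were lower. The called ribosomal protein gene was lost without WT 1 or WT 2, and the respiratory chain gene without WT 1, Mutant 1 or Mutant 2. Without WT 3, 5 cell cycle and 4 respiratory chain genes were lower, and 1 cell cycle gene was lower without any 1 other library. Scaling by library size only ended the call for ribosomal proteins (0.0784), the cell cycle (0.0648) and histones (0.0648). Thinning ended it for ribosomal proteins (0.0567) and histones (0.0567), and the stricter filter on CPM for histones (0.0525). Fry called none of these 4 lists (adjusted p = 0.636, 0.361, 0.268 and 0.374). Reads of ribosomal protein and histone genes can be shared with pseudogenes or near-identical copies. Of 17 mitochondrial tRNA synthetases 0 were higher and 1 lower in both counts, and 0 were lower without WT 1, Mutant 1 or Mutant 2. Their median was -0.05 and their mean 0.01, of opposite sign. Lars2, the member with the largest log2 fold change, stood at 1.33 ± 1.07 and was not called (edgeR adjusted p = 0.479). Its level was 17.5 ± 4.22 CPM in WT and 39.8 ± 45.5 CPM in Mutant cells, a wide spread between the Mutant libraries. The camera adjusted p of 0.0479 for the list became 0.221 with an estimated correlation and between 0.0511 and 0.145 without WT 1, WT 2, WT 3 or Mutant 1. It was 0.0767 with library size only, 0.0543 with the stricter filter on CPM and 0.0963 after thinning. Of 33 initiation and elongation factors edgeR, DESeq2 and limma-voom called 0. At an unadjusted edgeR p under 0.05, 0 were higher and 2 lower, with a camera adjusted p of 0.0964 and a fry adjusted p of 0.00555. Genes of the mitochondrial genome were not analysed here.

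Median log2 fold changes per chromosome lay between -0.02 on chromosome 12 and 0.02 on chromosome 6 for the autosomes and at 0.04 for the X chromosome. The X median was above all 10000 random gene sets of the same size and expression. Several autosomes also stood near the ends of such sets, with chromosome 7 at percentile 0.18, 12 at 0.63, 5 at 1.28 and 6 at 99.59. On the X chromosome 85 of its 459 tested genes were higher and 23 lower. It was 0.07 without Mutant 3 and 0.07 with scaling by library size only. Chromosomes 8 and 11, which are often gained in cultured mouse stem cells, had medians of -0.01 and -0.02. Of 3 tested Y-linked genes edgeR, DESeq2 and limma-voom called 0, and at an unadjusted edgeR p under 0.05 the counts were 0 higher and 1 lower. EdgeR called 1 lower without WT 3, and 0 higher and 2 lower with the replicate number as a block. The list was too short for camera. Xist, the RNA that silences an X chromosome, had 5 counts in all WT and 3 in all Mutant libraries.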

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

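Thinning to the smallest library was chosen after the depths were seen, and the other alternatives were planned. Counts of higher and lower genes stayed within 1.5 times of 1519 and 1038 in most alternatives, at 1296 and 837 after thinning, 1509 and 1074 with DESeq2 size factors, 1171 and 765 with DESeq2 and 1469 and 1054 with limma-voom. The replicate number as a block gave 2315 and 2596, so 47.1% of the calls were higher, against 59.4% without it. It called 2 ribosomal protein genes higher and 42 lower, 1 and 23 of the respiratory chain, 0 and 10 of the cell cycle, 0 and 9 histones, 1 and 14 initiation and elongation factors (camera adjusted p = 0.0424) and 2 and 3 cytosolic tRNA synthetases, while Hist1h4h was not called (0.0966) and camera did not call the stress response regulators (0.0806) or mitochondrial tRNA synthetases (0.0889). Among other lists, the block gave 0 higher and 10 lower mitochondrial chaperones and proteases, 1 and 9 heat shock genes and 5 and 6 glycolytic genes. It also gave 0 and 6 mitochondrial tRNA synthetases and 3 and 3 serine and one-carbon genes. The labels do not say that the numbers pair the samples, so the main fit has no block. Deviations from the group mean correlated at 0.061, 0.064 and 0.178 between samples of the same number, and each sample correlated best with its own number. An effect shared by samples of the same number is therefore not excluded, and the counts of the main fit depend on that choice. A required log2 fold change of 1 left 197 and 19, and the cause is the threshold itself. With fewer libraries, the count of higher genes ran from 1029 (without Mutant 2) to 1625 (without Mutant 3) and that of lower genes from 528 (without WT 2) to 1296 (without WT 3). The X chromosome median of 0.0439 moved to 0.0741 with library size only and ran from 0.0423 to 0.0664 with 1 library left out, and the cause was not tested. Of the alternatives to called named genes, 961 kept the call and 74 lost it, and 0 reversed. Trib3, which was not called, turned to 0.043 without WT 2 and 0.031 without Mutant 2, and ran from -0.148 (without WT 1) to 0.043. Of the alternatives for lists, 408 kept direction and side of the threshold, 60 lost the call, 9 gained one and 3 turned direction. Against 7 lists called higher and 11 lower by camera, library size only and thinning each gave 6 and 7, fry gave 10 and 8, a correlation estimated per list gave 0 and 0, and leaving out 1 library gave 6 to 7 and 7 (without WT 3 or Mutant 1) to 10 (without Mutant 3). The causes were not tested. The turned ones were not called in the first place. They were cytosolic tRNA synthetases without Mutant 3 (adjusted p = 0.84), which ran from 0.0511 (without WT 3) to 0.84, and glycolysis without WT 3 (0.705) and without Mutant 2 (0.955), which ran from 0.463 (without Mutant 3) to 0.955.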

Other observations

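The interferon, neighbouring-gene, edited-site, fibroblast, endoderm-share and thinning tests were chosen after the results they bear on were seen. Interferon-stimulated and antigen presentation genes were noticed among the genes higher in Mutant cells. All 23 noticed members were higher, from 0.352 to 2.423, with a median log2 fold change of 1.05, which is no independent evidence since they were picked for rising. They include Gbp2b, a guanylate-binding protein, at 1.07 ± 0.0538 (edgeR adjusted p = 6.17e-08), and Psmb8, an immunoproteasome subunit, at 1.04 ± 0.0776 (edgeR adjusted p = 1.53e-06). A second list of such genes was then written from members whose values had not been looked at. Of its 41 tested members 26 were higher and 2 lower, with a median log2 fold change of 0.356 (camera p = 1.31e-10, and p = 0.0016 with an estimated correlation). B2m, the light chain of MHC class I, stood at 0.64 ± 0.0874, Parp14 at 0.85 ± 0.1 and Irf1, a transcription factor of the pathway, at 0.35 ± 0.041. The transcription factors Stat1 and Stat2 stood at 0.28 and 0.24, while Irf9 at 0.03, Ddx58 at 0.03 and Adar at 0.06 were not called, and Pml and Ifitm2 fell by 0.18 and 0.14. Eif2ak2, the kinase PKR, belongs to the noticed list and, alone among its members, also to a list fixed beforehand. A candidate explanation is a low interferon-like tone in the Mutant cells, as a hypothesis from the same data. Clone, culture or genotype as its origin was not tested.

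Peg13, an imprinted noncoding RNA within the Trappc9 gene on chromosome 15 (72805600 to 72810324), was chosen after its values were seen. It stood at 2.6 ± 0.499 CPM in WT and 0.0606 ± 0.035 CPM in Mutant cells (edgeR adjusted p = 5.61e-07). Mutant 1 and Mutant 3 lay under the floor of 3 counts per library, which is 0.145 and 0.103 CPM there, so no fold change is given. Its host Trappc9 was not called (-0.05 ± 0.0829, edgeR adjusted p = 0.711). H19 and Peg13 thus moved in opposite directions, and Igf2, the neighbour of H19, rose only from 171.0 to 199.9 CPM.

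Eif2b5 counts were close to 0.51 times the WT level in Mutant cells. After thinning every library to the smallest total the log2 fold change was -0.996. Counts are scaled to library size in the fit, so random thinning hardly moves the fold change of a gene at this level. The value therefore does not test depth as a cause. A deletion of an allele that reaches a tested neighbour on either side is argued against by log2 fold changes of 0.027 ± 0.0477 for Abcc5 and 0.104 ± 0.0501 for Dvl3, the nearest ones. A deletion that ends before them is not. Failure to count reads over the edited codon would have to remove reads over about 1261 bases of a transcript of 2554 bases. Whether that exceeds the fragments cannot be told apart, because their length is not given in the sources used here. A change within or next to the gene, lower transcript stability or lower transcription in this clone stay open and untested.

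Endoderm markers had the largest median of the lists tested by camera. The median was 1.903 after thinning, which hardly moves fold changes already scaled to library size and so does not test depth as a cause. The trend of log2 fold change with length and GC had an SD of only 0.016 over tested genes. Removing it left the endoderm median at 1.907. Removal of so small a trend could not move a median of this size, so that step decides nothing. The small SD shows only that fold changes over all tested genes hardly followed length and GC. Fibroblast feeder cells are argued against as the source by the fibrillar collagens Col1a1, Col1a2 and Col3a1, abundant in such cells, whose summed rise was 3.7 CPM (SE 0.75) against 134.2 CPM (SE 5.3) for Col4a1, Col4a2 and Lama1, a ratio of 0.028 (SE 0.0057). Of the fibroblast list, Sparc is also made by endoderm. More spontaneous endoderm-like differentiation in the Mutant cultures may account for the group, with genotype, clone and culture state all open, as a hypothesis found on the same data.

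H19 rose by more than the median of the 13 called endoderm markers. Its log2 fold change was 3.039 after thinning, which again does not test depth as a cause. H19 lay 1.93 SD above those markers, whose log2 fold changes ran from 0.73 to 2.815 with a median of 2.034 and an SD of 0.513. This is inside the bound of 2 SD set for a larger endoderm share, so such a share and a change of imprinting in this clone cannot be told apart. No allele-resolved values were analysed here.

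The share of higher calls depends on the scaling and on whether the replicate number is taken as a block. Removing the trend with length and GC, whose SD over tested genes was 0.016, changed the sign of 0 called genes and left 59.4% above 0. A trend that small could hardly turn the sign of a called gene. The removal therefore does not test length and GC bias as the source of the share. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1519 higher and 1038 lower genes, and 1 of the 10 splits, the real one, gave as many in each direction. The highest other split gave 0 and 0 with edgeR, where between 67 and 882 genes had an unadjusted p under 0.05 and DESeq2 called at most 1. Every other split mixes WT and Mutant libraries in each group, so the difference between genotypes adds to the spread within groups. Few calls were due in them for that reason, and they do not show how often chance would give such counts. Camera called 18 lists in the real split and up to 9 in another, where 1 of the 10 splits again gave as many.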
